A study of Mus musculus with 22 samples.

How the data were processed

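The series holds 22 mouse retinal cells, each profiled alone on an Affymetrix mouse expression array. Per the labels, retinas were dissociated with papain, single cells were picked and lysed, their RNA was reverse transcribed from an oligo dT primer, and the cDNA was tailed and amplified by 35 cycles of PCR before labelling with biotin. The design text states that the cells were named only after profiling, as developing ganglion cells, amacrine cells or rod photoreceptors, so a difference in a marker of these types is not independent evidence of the type. No animal, litter, pool or hybridisation batch is named in the sources used here.

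The deposited values are signal intensity computed by the authors with MAS5, on a linear scale and without detection calls. The values themselves showed that 21 of the 22 arrays had a 2% trimmed mean of 500. The remaining array, P0 amacrine cell B1, had a trimmed mean of 18.1 and was multiplied by 27.6 to bring it to the same target. Scanner settings and the version of the probe set annotation the authors used are not given in the sources used here. No sequencing was involved, and scanner files were not used here.

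The table held 45101 probe sets, of which 64 were Affymetrix controls by name. A single gene symbol was listed for 34958 probe sets, several symbols for 932 and none for 9211. Of those with a single symbol, 34754 were matched by gene number to the RefSeq gene table, which was used for names only. Signals were raised to a floor of 200 (log2 7.64) and log2 transformed. The probe set with the highest mean over the 22 cells stood for each of 18194 genes. A gene at a signal of 1000 or more (log2 9.97) is called detected in that cell, and the 7184 genes detected in at least 3 of the 22 cells were tested. Between 1518 and 4352 genes were detected per cell, and the number of arrays limits the precision of every value. A difference against a group at the floor depends on that floor.

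Because cells of a type and stage may come from the same animal, cells were not taken as replicates. Their log2 values were averaged into 9 type-and-stage samples: ganglion cells of E12.5, E13.5, E14.5, E15.5 and P0, amacrine cells of E16.5 and P0, and photoreceptors of P0 and the adult. P0 samples of different types may still share an animal. A linear model with 1 mean per cell type was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, 6 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The prior degrees of freedom of eBayes were estimated as infinite, so the spread of each gene was taken from the trend over expression level. Ganglion cells were contrasted with amacrine cells (5 against 2 samples), and photoreceptors with the mean of the ganglion and amacrine means (2 against 5 and 2). Errors after ± are the standard error of the contrast unless another is named. Stage and type were partly confounded, since P0 alone held all 3 types, so no stage term was fitted.

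The comparisons of P0 ganglion with P0 amacrine cells, of the adult rod with P0 photoreceptors and of P0 with E12.5 ganglion cells set 1 sample against 1 and have no p-value. For these, the median log2 difference of a gene list is given with its percentile among 10000 random lists of equal size drawn from 20 bins of mean expression. Heterogeneity was described by Spearman correlations between cells across the tested genes and by the standard deviation (SD) of log2 signal between cells.

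The 18 gene lists were fixed before the data were examined: markers of ganglion cells, amacrine cells, photoreceptors, cones, bipolar cells, horizontal cells, Müller glia and astrocytes; progenitor and cell cycle genes; vascular, blood and immune genes; pigment epithelium and lens genes; neurogenic, axon growth, synaptic, neuropeptide and transmitter, housekeeping, ribosomal protein and stress genes; and transcription factors of retinal cell types. Lists of at least 2 tested genes were tested in the fit with camera of limma, with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of each contrast. Genes were named by a rule fixed at the same time. It took, for each contrast and direction, the 12 passing genes with the largest difference, or all passing genes filled up to 10 with the largest non-overlapping differences. To these it added the tested members of the marker list in question and up to 4 members of every other list. For P0 against E12.5 it took the 10 largest differences per direction among genes whose cells did not overlap. For heterogeneity it took the 10 largest SDs within the transcription factor and transmitter lists and among all genes, for genes detected in at least 3 cells and undetected in at least 3.

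The fit was tested on simulated data of 7184 genes with 200 changed genes, in 20 simulations per contrast. Each gene's 22 values were permuted over the cells, and shifts of either sign were added without applying the floor again. Permutation removes stage effects and the correlation between genes, so the rates below need not hold for the real data. For ganglion minus amacrine cells, the share of changed genes recovered was 8.96% at a log2 shift of 2, 52.2% at 4 and 94% at 6. For photoreceptors these shares were 12.9%, 54.9% and 87.1%. False calls made up 10.7% of calls in the first contrast and 14.3% in the second, above the nominal 5%, while data with no changed gene gave a median of 0 calls and at most 1 and 2.

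Alternatives fixed before the data were examined were deposited values without rescaling, quantile normalization, floors of 50 and 500, no filter and filters at 500 and 2000, the mean over a gene's probe sets, omission of probe sets ending in _x_at or _s_at, medians over cells, weights by number of cells, eBayes without trend and robust, and omission of each cell in turn. Detection levels of 500 and 2000, Pearson in place of Spearman correlation, pairs of the same or of different stages, and SDs within stages were also fixed then. After seeing the data, 4 more were added: omission of the adult rod with P0 amacrine cell B1, of ganglion stages E14.5 and E15.5, and of E14.5 alone, and gene-wise variances without moderation. Probe sets with several or no symbols were left out of the gene tables. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.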

Results

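Expression was measured in 22 single mouse retinal cells: 13 ganglion cells, the output neurons of the retina, 6 amacrine cells, its inhibitory interneurons, and 3 photoreceptors. The ganglion cells comprised 3 cells of E12.5, 1 of E13.5, 2 of E14.5, 3 of E15.5 and 4 of P0. Of the amacrine cells, 1 was taken at E16.5 and 5 at P0, and of the photoreceptors 2 at P0 and 1, a rod, from the adult. Ganglion cells held 3054 ± 781 detected genes (SD, n = 13 cells), amacrine cells 2877 ± 902 (SD, n = 6) and photoreceptors 2601 ± 418 (SD, n = 3). Over all 22 cells the number ran from 1518 in ganglion cell C7 of E15.5 to 4352 in ganglion cell F1 of P0, with a median of 2996.5. The highest Pearson correlation among the 231 pairs of arrays was 0.700, so no array was a copy of another. The adult rod stood apart, with a median Spearman correlation of 0.0721 to the other cells and 27.8% of its signal in 100 probe sets. It and amacrine cell J6, the only cell of E16.5, had high median signals over all probe sets, 192.1 and 197.7. In them 55.0% and 57.9% of genes lay above the floor. The highest values in any other cell were 79.1, in ganglion cell A6 of P0, and 37.2%, in ganglion cell F1 of P0.

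The first comparison, ganglion minus amacrine cells, addresses which genes separated these neurons, the subject named by the series title. Ganglion cells expressed more Ebf3, a transcription factor of ganglion cell development (log2 difference 6.52 ± 1.47, adjusted p = 0.0334 in limma), S100a10, a calcium-binding protein of the S100 family (6.21 ± 1.47, adjusted p = 0.0371), and Sncg, or gamma-synuclein, a marker of ganglion cells (6.06 ± 1.44, adjusted p = 0.0371). Amacrine cells expressed more Tfap2b (-6.15 ± 1.21, adjusted p = 0.00293) and Tfap2a (-4.02 ± 0.95, adjusted p = 0.0371), AP-2 transcription factors of amacrine cells. Ebf3 was detected in 13 of 13 ganglion and 0 of 6 amacrine cells, and Tfap2b in 0 of 13 ganglion and 6 of 6 amacrine cells. Mean log2 signals were 14.30 against 7.77 for Ebf3 and 7.64, the floor, against 13.79 for Tfap2b. These 5 genes, 3 higher and 2 lower in ganglion cells, were all that passed among 7184 tested in 5 against 2 type-and-stage samples. The count ran from 1 to 9 when each cell was left out in turn, and from 0 to 31 over the alternatives in processing. Tfap2b passed in all 22 fits that left out 1 cell, but Ebf3 in 16, Tfap2a in 11, S100a10 in 10 and Sncg in 9 of them. These tallies include the fits without the adult rod and without amacrine cell J6, which leave a single sample in a group. For S100a10 and for Tfap2a, 1 of 3 probe sets lay within 1 of 0.

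Other large differences in favour of ganglion cells did not pass: Vim, an intermediate filament (5.44 ± 1.45, adjusted p = 0.119), Elavl4, a neuronal RNA-binding protein (4.99 ± 1.46), Syt13, a synaptotagmin (4.80 ± 1.46), Rbpms, an RNA-binding protein of ganglion cells (4.54 ± 1.45), Gng2, a G protein subunit (4.21 ± 1.45), Nefl, the light neurofilament (4.04 ± 1.45), and Ddah2 (3.92 ± 1.46). On the amacrine side, Gad1, an enzyme that makes the inhibitory transmitter GABA, was at -5.52 ± 1.40 (adjusted p = 0.0782), with detection in 6 of 6 amacrine and 0 of 13 ganglion cells. Sox2ot, a transcript overlapping Sox2, was at -4.35 and Megf10, a receptor of starburst amacrine cell spacing, at -4.34, both with an adjusted p of 0.0782. Slc18a3, the vesicular acetylcholine transporter, was at -3.27 ± 0.85 (adjusted p = 0.0846). Car2, carbonic anhydrase 2 (-4.52), Cacng3, an AMPA receptor auxiliary subunit (-3.92), Qk, an RNA-binding protein (-3.89), Irs1, an insulin receptor substrate (-3.63), and Ypel2 (-3.63) did not pass either.

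The ganglion marker list was higher in ganglion cells as a set, with a median of 3.48 over 13 tested genes (camera adjusted p = 2.7e-16; adjusted p = 0.00445 with an estimated correlation). Of its genes, 2 passed over all genes tested and 9 when adjusted over the list alone. They included Nefm, the medium neurofilament (mean log2 14.35 against 10.35), Gap43, a growth cone protein (3.53), Slc17a6, a vesicular glutamate transporter (3.48), Pou4f1, a POU-domain factor (3.27), and Nrn1, a neurite growth factor (2.87), while Eya2 was at 2.14, Ebf1 at 1.56, Pou4f3 at 0.67 and Isl1, which changed sign with processing, at -0.80. The amacrine list was lower by camera, with a mean of -1.59 over 9 genes (adjusted p = 9.94e-05, or 0.0313 with an estimated correlation). Its median of -0.26 lay at percentile 32.1 of random lists matched on mean expression, so its typical member was not clearly lower. Of its members 6 were negative and 3 positive, with 2 lower over all genes tested and 4 adjusted over the list alone. Its members Pax6 (-0.18), Barhl2 (-0.26) and Meis2 (0.29), each of which changed sign with processing, lay near 0, and Tcf4 (2.55) and Calb2, the calcium-binding protein calretinin (2.27), had the opposite sign. Without the ganglion cell of E13.5 the median of the amacrine list was -1.21, and without the amacrine cell of E16.5 it was -1.11. Both lists may overlap the markers used to name these cells, so their direction is not independent evidence. The axon growth list had a median of 0.88 over 26 genes (camera adjusted p = 0.00246; adjusted p = 0.195 with an estimated correlation). None of its members passed over all genes or adjusted over the list alone, and its largest values were Nrp1, a semaphorin receptor (3.42), Cntn2, an axonal adhesion molecule (3.28), L1cam, another (2.89), and Plxna2, a plexin (-2.84).

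No other list passed in this contrast. The nearest were horizontal cell markers, which include Tfap2b (median -0.23, mean -1.66, adjusted p = 0.0668), ribosomal protein genes (0.38, adjusted p = 0.0674) and neuropeptide and transmitter genes (1.03, adjusted p = 0.118), among them Gal, the peptide galanin (2.34). Medians were 0.64 for progenitor and cell cycle genes, 2.03 for vascular, blood and immune genes, 0.41 for stress genes, 0.29 for glial markers, -1.13 for bipolar markers, 0.23 for synaptic genes, 0.49 for retinal transcription factors and -0.05 for housekeeping genes, with camera adjusted p between 0.213 and 0.961. Neurogenic genes (median 0.05, mean -0.14) and photoreceptor markers (median 0.05, mean -0.15) had medians of the opposite sign to their means and tests. Among neurogenic genes Neurog2, a proneural factor, was at -3.03 and Sox11, a factor of immature neurons, at 2.94. The cone list had the single tested gene Rxrg (0.75), and the pigment epithelium and lens list the single tested gene Cryaa, a lens crystallin (2.44).

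Lens and blood transcripts moved with some of the ganglion samples. Cryaa was at 14.8 and 15.1 in the ganglion cells of E14.5 and at 12.52 in that of E13.5, and the embryonic globin Hbb-y (3.02 in the contrast) was detected in 5 of 5 ganglion cells of E14.5 and E15.5 and in 0 of 17 other cells. Without the E14.5 sample 1 gene passed, and without both stages none did in limma. The count was also 1 without P0 photoreceptor H1 or E1, which lie outside this contrast. These falls therefore cannot be tied to the lens and blood transcripts. The group means of 612 genes did not overlap, 8.52% of those tested against 9.52% from chance, and 283 genes had an unadjusted p under 0.05.

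**Figure D1:**
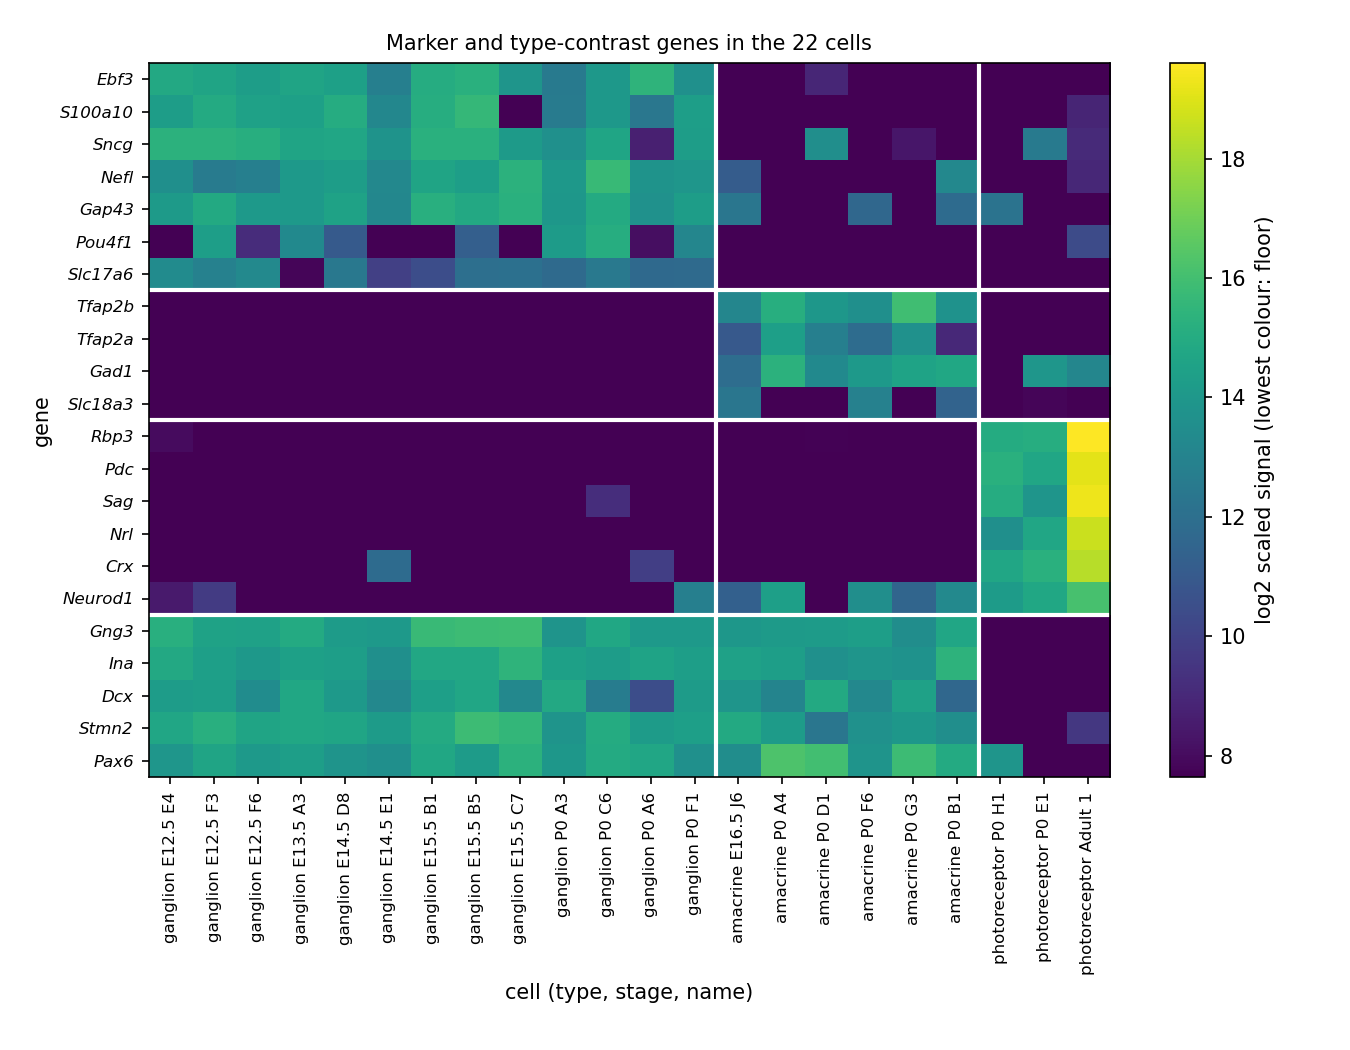
Log2 scaled signal of 22 genes in the 22 cells, 1 cell per column, with white lines between cell types and between gene groups and the darkest colour at the floor of 7.64. Ebf3 was detected in 13 of 13 ganglion cells, Tfap2b in 6 of 6 amacrine cells and Rbp3 in 3 of 3 photoreceptors, while Gng3 was at the floor in all 3 photoreceptors.

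Within P0, where 4 ganglion cells stood against 5 amacrine cells, the ganglion marker list was 4.29 higher in ganglion cells, at percentile 100 of matched random lists. Nefl (5.59), Nrn1 (5.34), Rbpms (5.29), Pou4f1 (4.99), Gap43 (4.94), Slc17a6 (4.29) and Sncg (3.86) led it together with Ebf3 (mean log2 13.90 against 7.90). The amacrine list was at -1.50 (percentile 0.085), with Tfap2b at -6.83, Gad1 at -6.77 and Tfap2a at -4.73, while its member Calb2 was at 4.54. Nhlh2, a neuronal basic helix-loop-helix factor, was at -5.30, being at the floor in the 4 ganglion cells and detected in 4 of 5 amacrine cells. The median of all tested genes was 0.23. Synaptic genes were at 1.15 (percentile 99.1), with Scn3a, a sodium channel, at 3.67 and Syt4, a synaptotagmin, at 3.09, and axon growth genes at 0.86 (percentile 98.4), with Map1b, a microtubule protein, at 3.40 and L1cam at 3.38. Progenitor and cell cycle genes were at -0.69 (percentile 0.98), with Sox2, a progenitor factor, at -2.91, and neurogenic genes at -0.58 (percentile 4.55), with Sox4 at -2.41 and Insm1 at -2.23.

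With 1 sample on each side, these P0 values have no p-value. The amacrine list was at -0.28 with medians over cells and at -0.83 without amacrine cell A4 and -0.94 without G3, and the ganglion list at 2.34 with no filter on dim genes.

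The next contrast set photoreceptors against ganglion and amacrine cells. Genes of photoreceptor function were higher in photoreceptors: Rbp3, a retinoid carrier (9.67 ± 1.38, adjusted p = 1.54e-08), Pdc, or phosducin (9.40 ± 1.37), Sag, the rod arrestin (9.19 ± 1.37), Nrl, a rod-determining factor (8.75 ± 1.35), Crx, a photoreceptor homeobox factor (8.74 ± 1.39, adjusted p = 3.02e-07), Rom1, a disc protein (8.70 ± 1.37), Cdhr1, a photoreceptor cadherin (8.55 ± 1.36), and Pde6b, a rod phosphodiesterase subunit (8.48 ± 1.34). Prom1, a disc membrane protein (7.86), Plekhb1, a pleckstrin homology protein (7.81), Pitpnm3 (7.47) and Tulp1, a photoreceptor tubby-like protein (7.32), followed. Each of these 12 genes was detected in 3 of 3 photoreceptors. For those detected in no ganglion or amacrine cell, such as Rbp3, Pdc, Sag and Nrl, the filter on 3 cells required this in advance. Among the genes lower in photoreceptors were Ina, an intermediate filament (-6.76 ± 1.32, adjusted p = 0.00012), Kif5c, a kinesin (-6.37 ± 1.34), Dcx, or doublecortin (-6.16 ± 1.37), Tubb2b, a tubulin (-6.14 ± 1.29), Stmn2, a stathmin (-5.88 ± 1.27), and Map2, a dendritic microtubule protein (-5.53 ± 1.33). Probe sets of a gene did not all agree. For Rbp3 1 of 2 lay within 1 of 0, and its difference was 4.83 with the mean over probe sets. So did 1 of 4 for Pitpnm3, 3 of 4 for Kif5c and for Map2, and 2 of 4 for Dcx, which did not pass with the mean over probe sets (adjusted p = 0.305). In all 152 genes passed in limma, 108 higher and 44 lower, in 2 photoreceptor samples against 5 and 2. The errors above come from the trend and not from each gene's own spread. Over the 2 photoreceptor samples the SD was 3.98 for Pde6b and 3.21 for Rbp3. In the linear model with gene-wise variances, Pde6b (adjusted p = 0.0767), Prom1 (0.125) and Vdac3 (0.388) did not pass. Rbp3, Pdc, Sag, Nrl, Crx, Rom1, Cdhr1 and Plekhb1 passed there, at adjusted p from 0.0107 to 0.0336.

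Also lower in photoreceptors were Gng3, a neuronal G protein subunit (-6.78 ± 1.30, adjusted p = 8.53e-05), Nnat, or neuronatin (-6.43), Tagln3 (-6.31), 6330403K07Rik (-6.24), Crmp1, a collapsin response mediator (-5.46), and Vdac3, a mitochondrial channel (-5.36, adjusted p = 0.0157). Of transcription factors, Pax6, an eye master regulator, fell by 5.15 (adjusted p = 0.00674) and Sox4 was at -5.20 (adjusted p = 0.00448), although P0 photoreceptor H1 held both, at 13.9 and 14.89, and Neurod1, a factor of photoreceptors and amacrine cells, was higher (5.42, adjusted p = 0.0138). The synaptic vesicle genes Sv2b (6.69, adjusted p = 0.000651) and Syp, or synaptophysin (5.03, adjusted p = 0.016), were higher too, and so were Clu, or clusterin (5.94, adjusted p = 0.00175), of the glial list and Septin4 (5.38, adjusted p = 0.0106) of the horizontal cell list. With the adult rod left out, which leaves a single photoreceptor sample, Sv2b was at 3.12, Syp at 4.19, Clu at 2.17 and Septin4 at 0.83. Clu was at the floor in P0 photoreceptor E1 and Septin4 in H1. Otx2, a photoreceptor homeobox factor, was at 2.94 (adjusted p = 0.0874), Unc119 at 3.77 (adjusted p = 0.169) and Gnb1, a G protein subunit, at 0.96 (adjusted p = 0.693). Gnb1 had the opposite sign without the adult rod, at -3.36.

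The photoreceptor list was higher as a set, with a median of 8.59 over 12 genes (camera adjusted p = 6.5e-42; adjusted p = 0.0202 with an estimated correlation), and 9 of its genes passed over all genes tested and 11 adjusted over the list alone. Its median was 4.07 without P0 photoreceptor E1, 5.13 without H1 and 5.35 without the adult rod, each over fewer genes. This list, too, may overlap the markers used to name the cells. Only 12 of its 27 measured genes were tested. Members detected in no ganglion or amacrine cell were tested only if every photoreceptor held them, which favours high differences. Axon growth genes were lower by camera, at a median of -1.65 over 26 genes (adjusted p = 8.42e-05; adjusted p = 0.12 with an estimated correlation), with 6 lower over all genes tested and 8 adjusted over the list alone. Ganglion markers were at -1.76 (adjusted p = 0.0153; adjusted p = 0.228 with an estimated correlation), with Nefm lower over all genes tested (-4.70, adjusted p = 0.0444) and 5 genes lower adjusted over the list alone. Ribosomal protein genes were at 1.22 (adjusted p = 0.0053; adjusted p = 0.649 with an estimated correlation) with no gene passing in either way. Of the housekeeping list, Tmsb4x, an actin-binding thymosin (-4.16, adjusted p = 0.0131), and Ywhaz, a 14-3-3 protein (-3.86, adjusted p = 0.0462), passed, but both were at the floor in the adult rod. Without it they were at -0.60 and -0.62. The tests of the remaining lists did not pass. The tests of glial markers (median -0.93, mean 0.46), horizontal cell markers (median -2.33, mean -0.01), synaptic genes (median -0.51, mean -0.11), progenitor and cell cycle genes (median -0.12, mean -0.20) and housekeeping genes (median 0.22, mean -0.04) pointed up, against the sign of the median, the mean or both.

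The adult rod weighed on this contrast. Leaving out the rod, or the E16.5 amacrine cell, leaves a single sample in its group. The spread then comes from the other groups, so only differences are given. Without the rod, Prom1 was at 5.40 and Neurod1 at 4.59. Rbp3, Pdc, Sag, Nrl, Cdhr1, Pde6b, Plekhb1, Pitpnm3 and Tulp1 were then detected in too few cells to be tested. The group means of 725 genes did not overlap, 10.1% of those tested against 5.56% from chance. The P0 photoreceptors also differed from each other: H1 held 5 of 5 glial markers (mean log2 13.40), 8 of 13 progenitor and cell cycle genes (10.73) and 7 of 9 stress genes (12.13), and E1 held 0 of 5 (7.64), 0 of 13 (7.67) and 3 of 9 (9.44).

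Setting the adult rod against the P0 photoreceptors, the photoreceptor list was 3.93 higher in the adult (12 genes, percentile 100), with Pde6b at 5.62, Sag at 4.82, Rbp3 at 4.54, Nrl at 4.47, Pdc at 4.17 and Rom1 at 3.69. Crx was at 3.33, Neurod1 at 1.65 and Tulp1 at 1.58, and these 3 genes turned to -0.39, -1.29 and -1.17 after quantile normalization. Synaptic genes were at 1.57 (percentile 99.98), with Nsf, a vesicle fusion ATPase, at 10.30, Rab3a, a vesicle GTPase, at 8.51 and Sv2b at 7.15. Neurogenic genes were at -2.97 (percentile 0.26), with Insm1 at -5.70 and Sox4 at -3.62, and Otx2 was at -6.34, at the floor in the adult rod. The P0 cells disagreed: their neurogenic means were 9.24 and 12.19, against 8.30 in the adult rod. Among the photoreceptors, only P0 cell H1 held Sox4. Meis1, a homeobox factor, was at 7.58, and the housekeeping and ribosomal lists were at 3.14 and 2.69. With a single adult cell, there is no spread for these values. After quantile normalization the photoreceptor list was at 0.48, and without P0 cell H1 it was at 2.23.

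Stage within ganglion cells was examined between E12.5 (3 cells) and P0 (4 cells). At P0, synaptic genes were 0.95 higher (21 genes, percentile 99.1), among them Gria2, an AMPA receptor subunit (4.45, detected in 4 of 4 against 0 of 3 cells), Syt4 (3.61) and Syt1, the calcium sensor of release (2.77). The largest differences in favour of P0 among genes whose cells did not overlap were Sphkap, an anchoring protein (5.48), Acp1, a phosphatase (5.19), Lgalsl (5.08), Tomm70a, a mitochondrial import receptor (5.07), Nap1l5 (5.06), Ranbp6 (5.04), Calb2 (4.95), Slc36a4, an amino acid transporter (4.93), Rit2, a neuronal GTPase (4.91), and Cblb, a ubiquitin ligase (4.90). In favour of E12.5 they were Ints6, an Integrator subunit (-6.64), Crabp1, a retinoic acid binding protein (-6.48), Csrp2 (-5.06), Cnr1, a cannabinoid receptor (-5.04), Armh4 (-5.04), Elovl5, a fatty acid elongase (-4.89), P2rx3, an ATP receptor (-4.77), Pmvk (-4.72), Grb10 (-4.63) and Cotl1, an actin-binding protein (-4.63). Crabp1 stood at 14.98, 15.52 and 15.72 at E12.5, E13.5 and E14.5 and at 10.01 and 8.50 at E15.5 and P0.

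Axon growth genes as a list were at -0.20 (26 genes, percentile 16.5), with Nrp1 at -4.41 beside Map1b at 3.26 and Dcc, a netrin receptor, at 2.87. Neurogenic genes were at -0.16 (percentile 34.6), with Sox11 at -3.98 and Hes6 at -2.64, and progenitor and cell cycle genes at 0 (percentile 36.1), with Fgf15 at -3.19 and Pcna, a replication clamp, at -3.03. Members such as Mcm2 and Sox2 were at the floor in every cell of both stages, so this median of 0 does not show unchanged expression. It was -1.60 without the E14.5 and E15.5 cells, which changes the genes tested. Pcna was at 14.64 in P0 cell C6, above every E12.5 cell, and at 7.64 to 8.05 in the other P0 cells. Retinal transcription factors were at -0.54 (percentile 1.8), with Nhlh2 at -4.04 and Satb1 at 3.46. Ribosomal protein genes were lower at P0, at -1.52 over 24 genes (percentile 0), and their mean per cell lay between 11.47 and 13.42 at P0 and between 14.08 and 14.19 at E12.5. Rps29 (-4.12), Rpl38 (-4.01), Rpl41 (-3.58) and Rps15 (-3.57) were furthest apart, while housekeeping genes were at 0.26 (percentile 70.2). Between these stages, the E14.5 sample stood out in progenitor and cell cycle genes, at a mean of 11.87 against 8.24 to 9.04 at the other ganglion stages, and it was the sample with the lens transcripts given above.

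These stage differences have no p-value, since each stage is 1 sample. The synaptic list was at 0.082 without P0 cell F1 and at 0.092 with the mean over probe sets, and its member Syt11 was at -3.60 but at 0.30 with values as deposited. By leave-one-out the neurogenic list ran from -0.85 without P0 cell C6 to 0.018 without A6, and the axon growth list from -0.34 without C6 to -0.064 without E12.5 cell E4.

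**Figure D2:**
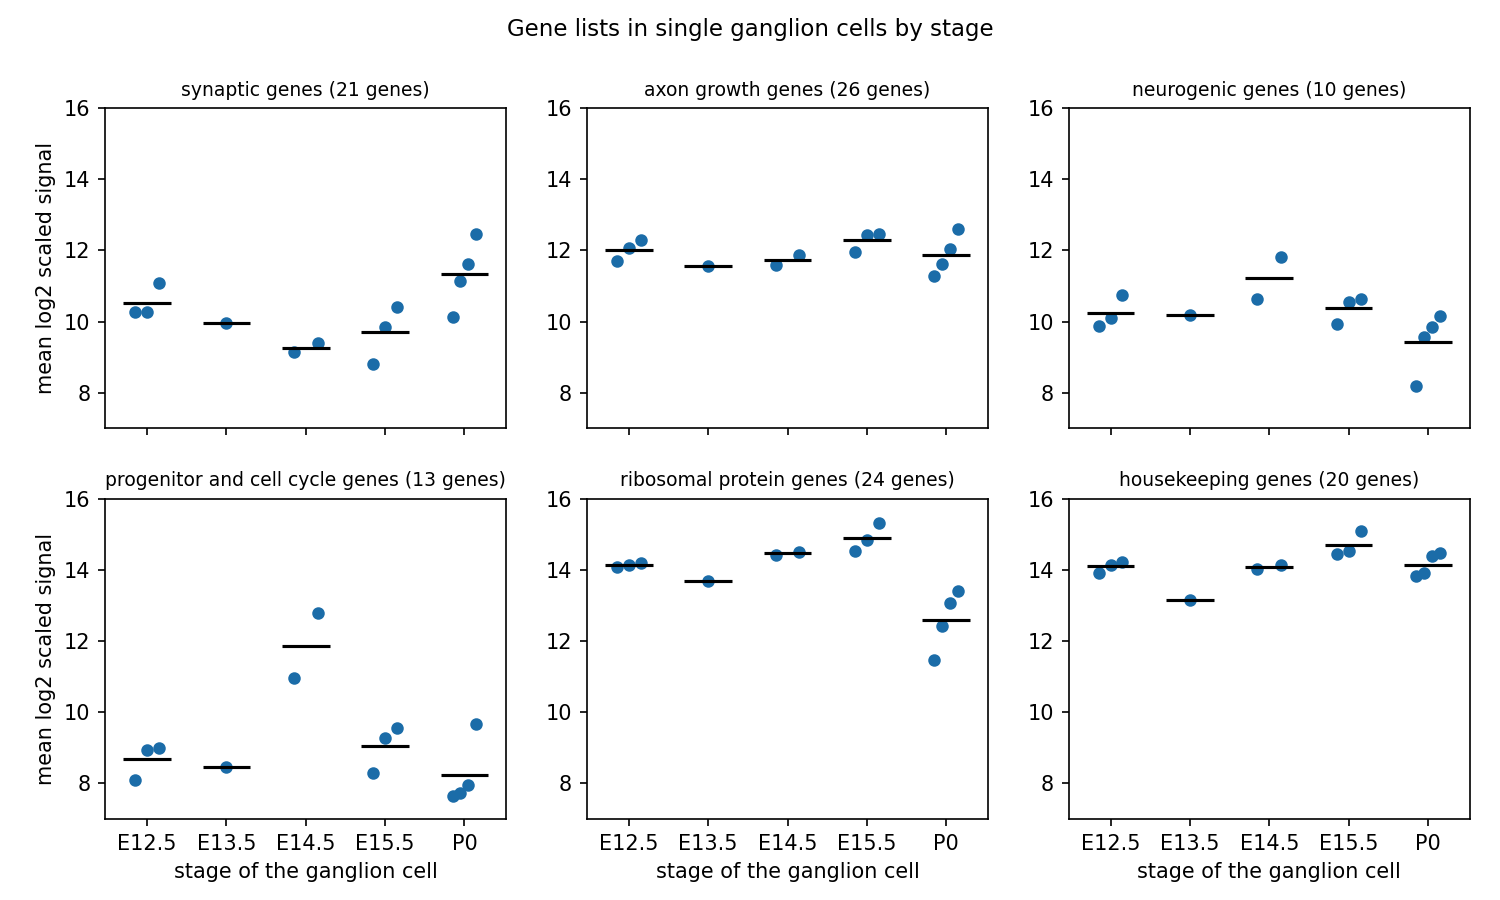
Mean log2 scaled signal of 6 gene lists in each of the 13 ganglion cells (points) by stage, with the stage mean as a black line. Ribosomal protein genes lay between 11.47 and 13.42 in the 4 cells of P0, and progenitor and cell cycle genes averaged 11.87 at E14.5.

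The series title asks about heterogeneity within types. Ganglion cells shared 201 tested genes detected in all 13 cells, and 6860 were detected in some but not all of them. For the 6 amacrine cells these numbers were 371 and 5771. Stage is mixed into these numbers, since the ganglion cells span 5 stages. Ganglion cells differed from each other in transcription factors: Pou4f1 was detected in 7 of 13 cells (SD 2.95), Isl1 in 10 (SD 2.59), Meis1 in 8 (SD 2.90), Nhlh2 in 8, none of them of P0 (SD 2.69), Irx2 in 6 (SD 2.49), and Irx3 (SD 2.47), Nr2f2 (SD 2.56) and Zfhx4 (SD 2.56) in 4 each. Calb2 was detected in 6 (SD 3.12) and Cnr1 in 8 (SD 2.86). Among all genes the largest SDs were those of Hbb-y (4.07) and Crabp1 (3.81), followed by Enoph1, Snhg11, Dnm1l, Anp32b, Armcx4, Cntn2, Lztr1 and Meg3, at 3.13 to 3.24. The median SD of the transcription factor list was 2.07 (40 genes, percentile 96.7 of matched lists). That was little above the 1.94 of matched random lists and the 1.90 of all tested genes. Ribosomal protein genes were at 1.58 (percentile 43.3), housekeeping genes at 0.95 (percentile 0.26) and axon growth genes at 1.46 (percentile 0.16). Percentiles above that of the transcription factors were those of progenitor and cell cycle genes (2.05, percentile 98.5), of vascular, blood and immune genes (2.70, percentile 99.5) and of the lens gene Cryaa (2.91, percentile 99.7). Transmitter genes were at 1.92 (percentile 19.3).

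Within the transcription factor and transmitter lists, amacrine cells differed most in Nr4a2, a nuclear receptor (SD 3.98), and Isl1, a LIM homeobox factor (SD 3.88). Isl1 was at 14.8 in cell J6 of E16.5, at 14.5 in F6 and at 14.9 in B1 of P0, and at the floor in A4, D1 and G3. Nr4a2 was at 13.2 in A4, 16.3 in D1 and 14.5 in G3, and at the floor in the other 3 cells. Sox2 (SD 3.99), Sox2ot (SD 3.71), Megf10 (SD 3.63), Plagl1, a zinc finger factor (SD 4.04), Rims1, a presynaptic active zone protein (SD 3.72), and Cnr1 (SD 2.79) were detected in the cells with Isl1, and so was Slc18a3, at 12.4, 12.9 and 11.5 in J6, F6 and B1. Chat, the enzyme that makes acetylcholine, reached the detection level only in B1, at 13.9. The values of B1 rest on its rescaling by 27.6. As deposited, Isl1 was at 10.09 in B1 and stayed detected, as did Sox2, Megf10, Rims1 and Plagl1, but Chat (9.09), Sox2ot (9.61), Slc18a3 and Cnr1 were below the detection level. The floor and detection level were kept, so this only sorts the genes of B1 by signal. It does not test whether the rescaling is right. Wtap, Cbln2, Rap1a, Zfhx3, Nr2f2, Mef2a, Klf7, Meis1 and Satb1 were also detected in 3 of the 6 cells.

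The detection pattern of Isl1 was held by 192 genes, Isl1 included, and that of Nr4a2 by 16, Nr4a2 included. The median over the 20 possible patterns of 3 cells was 37 and the highest 243, for J6, F6 and G3. The median SD of the transcription factor list between amacrine cells was 1.73 (percentile 47.7) and that of transmitter genes 0.77 (percentile 37.3), against 0.95 for housekeeping genes (percentile 0.92), 2.24 for progenitor and cell cycle genes (percentile 100), 2.36 for synaptic genes (percentile 99.4) and 2.71 for glial markers (percentile 98.9). The value of transmitter genes was 0 without F6. J6 and F6 had the most detected genes of the amacrine cells, 3718 and 4132, and detection patterns also carry amplification noise.

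**Figure D3:**
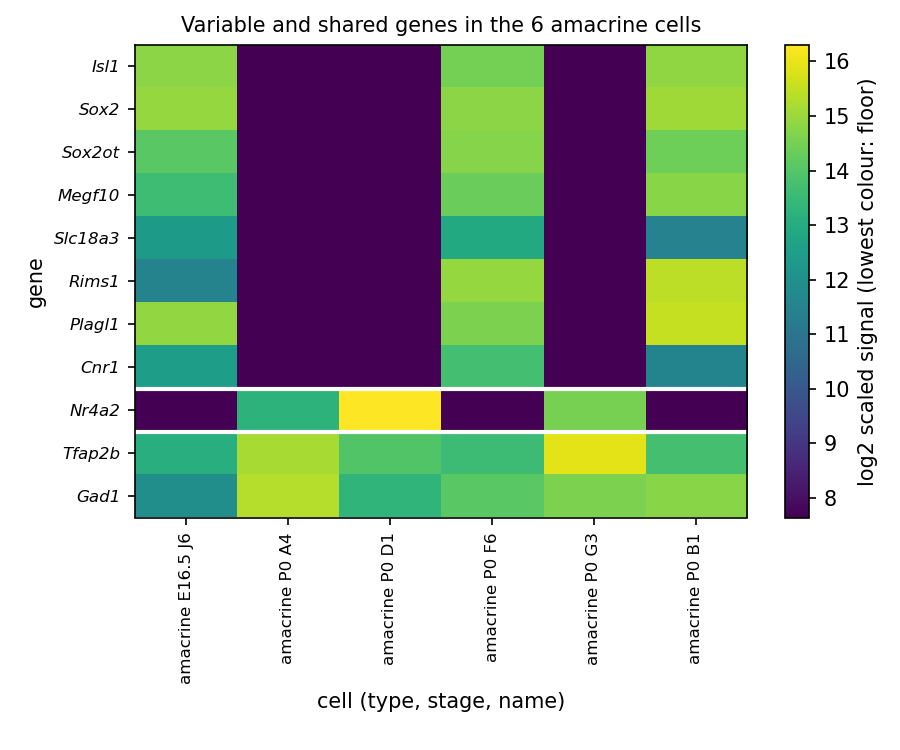
Log2 scaled signal of 11 genes in the 6 amacrine cells, 1 cell per column, with the darkest colour at the floor; the genes in the upper block were chosen because they share the pattern of Isl1. Isl1 lay between 14.5 and 14.9 in J6, F6 and B1, while Tfap2b and Gad1 were detected in all 6 cells.

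Whole profiles of single cells were only loosely alike. The median Spearman correlation across genes was 0.293 between ganglion cells (78 pairs), 0.271 between amacrine cells (15 pairs) and 0.254 between ganglion and amacrine cells (78 pairs). Photoreceptors were less alike than that, at 0.119 between each other (3 pairs), 0.162 with ganglion cells and 0.166 with amacrine cells. Their own pairs ran from 0.0949 to 0.246, and most of these include the adult rod, whose median correlation to all other cells was 0.0721. At P0 the medians were 0.314 between ganglion cells, 0.251 between amacrine cells and 0.236 across the types, and ganglion cells of the same stage had a median of 0.342 (13 pairs). Pairs share cells and genes are not independent replicates, so no test was made.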

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

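The tests of the lens transcripts below were chosen after the result was seen. A search for a cell far from the others of its type and stage was made in 78 combinations of group and measure and found 19, where chance gives about 1 in 20. That rate does not hold where all other cells are at the floor, as in most of these, because any cell above the floor is then found.

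The P0 ganglion cell A6 stood apart in the cone list (7.64, others 11.77 to 12.43), in Crmp1 (10.64, others 14.20 to 14.93), and in traces of the photoreceptor genes Crx (9.88), Cdhr1 (9.85), Rom1 (8.48) and Nrl (7.67), which were at the floor in the other P0 ganglion cells. P0 ganglion cell C6 stood apart in progenitor and cell cycle genes (9.66, others 7.64 to 7.95) and in Sag (9.20, others at the floor), and P0 ganglion cell A3 in the vascular, blood and immune list (7.90, others at the floor). P0 amacrine cell D1 stood apart in Sncg (13.54, others 7.64 to 8.38), in the bipolar list (14.84, others 10.30 to 11.13) and in Tagln3 (10.85, others 14.35 to 14.60), and had low signals of Ebf3 (8.94), Tulp1 (8.38), Rbp3 (7.73) and Cdhr1 (7.69) where the others were at the floor. P0 amacrine cell B1 stood apart in its deposited trimmed mean (18.1, others 500), in stress genes (8.41, others 9.65 to 10.11) and in Pde6b (8.27, others at the floor). Among the 10092 probe sets outside the gene tables, 1009 were tested, and 12 passed in the photoreceptor contrast in limma, 7 higher and 5 lower.

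Lens transcripts were present in both ganglion cells of E14.5. Of the 9 lens genes fixed in advance, 7 were detected in each of these 2 cells and at most 1 in any other. Only Cryaa, also detected in ganglion cell A3 of E13.5 (12.52), was held by enough cells to be tested in the fit. Mip, a lens channel that is not a crystallin, was at 12.13 in the lower of the 2 cells. Cross-hybridisation between crystallin probe sets would not account for Mip. But Mip is 1 of the 9 genes that showed the pattern, so its signal was already known. It also cannot show whether crystallin probe sets cross-hybridise with each other, so that stays open for the crystallins. RNA from lens cells, carried over in the dissociated suspension, may be the source. Of 8 lens genes outside the list, 5 were detected in D8 and 7 in E1, among them the membrane protein Lim2 (13.89 and 12.63) and the connexin Gja3 (12.30 and 10.34), and at most 1 in any other cell. Other non-crystallins were Bfsp1, at the floor in both cells, and Bfsp2, at the floor in D8 and at 11.12 in E1. Pigment genes were detected in neither cell. They were detected in all 3 photoreceptors: Pmel in H1 (12.35), Dct in E1 (13.82), and Mitf (17.39) and Ttr (10.36) in the adult rod. Outside the photoreceptors, only Mitf in ganglion cell A3 of E13.5 (10.49) reached the detection level. A state of E14.5 retinal cells cannot be told apart from shared handling, because all cells of this stage have the signal and the next highest ganglion cell held 1 lens gene.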

How the results depend on the processing

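The tests that leave out the adult rod with amacrine cell B1, ganglion stages E14.5 and E15.5, or E14.5 alone, or that use gene-wise variances, were chosen after the data were seen. No paired analysis was possible because the labels name no animal and replicate numbers only follow the order of deposition. The causes of the shifts below were not tested, except where fewer samples or another number of genes by construction enter a setting. Signals near the floor limit every difference, and a group at the floor gives no upper bound. Without the adult rod or amacrine cell J6, the photoreceptor or amacrine group has a single sample. Counts and tests in those fits rest on the spread of the other groups and are not read as calls. The tallies and ranges over settings below still include these fits.

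Ganglion markers, ganglion minus amacrine, and photoreceptor markers kept direction and test in all 15 alternatives (2.14 to 4.05 and 5.39 to 10.08) and without each cell. The photoreceptor median was 4.07 without P0 photoreceptor E1, 5.13 without H1 and 5.35 without the adult rod. The amacrine list kept its test, and its median ran from -1.21, without A3 of E13.5, to -0.17, without F6 of E12.5, by leave-one-out, but its median was 0.011 with values as deposited, with the test pointing down (adjusted p = 0.00258; 0.00874 at most over its alternatives). Tfap2b passed in 36 of 38 settings, Ebf3 in 27, Tfap2a in 19, and Sncg and S100a10 in 18 each.

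Genes passing in ganglion minus amacrine numbered 2 as deposited, 10 after quantile normalization, 1 with floor 500, 31 with no filter, 1 with the mean over probe sets, 0 with medians over cells in limma, 24 with samples weighted by cells, 9 without the adult rod and B1, 0 without E14.5 and E15.5, 1 without E14.5 and 8 with gene-wise variances. Genes passing in the photoreceptor contrast numbered 56 with no filter, 44 with the mean over probe sets, 47 with medians, 61 weighted, 70 without the adult rod and B1, 67 without E14.5 and E15.5, 99 without E14.5 and 51 with gene-wise variances. Leaving out each cell gave 1 to 9 genes in the first contrast, and 16 of the 22 cells moved its count by over 1.5 times. It was 1 without photoreceptor H1 or E1 of P0 or ganglion cell A3 of E13.5 or B1 or B5 of E15.5, 2 without amacrine cell F6 of P0 or ganglion cells F3 of E12.5, E1 of E14.5, or C6 or F1 of P0, and 3 without amacrine cell J6 or ganglion cell D8. It was 8 without amacrine cells A4 or G3 or the adult rod, and 9 without D1. The second contrast gave 45, without amacrine cell J6, to 161, and 68 without the adult rod.

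At P0 the ganglion list was at 5.01 after quantile normalization, 5.89 with floor 50, 3.02 with floor 500, 2.34 with no filter, 3.35 with the mean over probe sets and 5.64 with medians. The amacrine list was at -0.80 as deposited, -0.69 with no filter and -0.28 with medians, and -2.18 without D1 to -0.83 without A4. The photoreceptor list, adult minus P0, was at 0.48 after quantile normalization, 5.62 with no filter, 4.17 with the filter at 2000 and 3.11 with the mean over probe sets, and 2.23 without H1 or 3.56 without E1. The synaptic list, P0 minus E12.5 ganglion cells, was at 0.092 with the mean over probe sets, and 0.082 without F1 to 1.09 without A6, while neurogenic genes ran from -0.85 to 0.018 and axon growth genes from -0.34 to -0.064. Progenitor and cell cycle genes were at -1.60 without E14.5 and E15.5.

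Detected genes per cell were 1926 with the mean over probe sets. With no filter the Spearman correlations were 0.416 between ganglion cells and 0.374 across types, and amacrine pairs of different stages had 0.338. The SD of transcription factors in ganglion cells was 2.53 with floor 50, 1.62 with floor 500, 1.43 with no filter and 1.31 with the mean over probe sets, and in amacrine cells 2.39 with floor 50 and 0.59 with no filter. The SD of transmitter genes was 1.31 with floor 500 and 0.17 with no filter in ganglion cells, and 1.05 after quantile normalization, 0.32 with floor 500, 0.39 with no filter and 0 to 0.84 without each cell, 0 being without F6, in amacrine cells.

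Single genes turned sign in 41 values, each a single gene in a single comparison and setting. As deposited, Pax6 was at 0.30 and Syt11 at 0.30, the latter also without the adult rod and B1 (0.30) and at 0.13 with floor 50. The value of 0.30 for Syt11 comes from another probe set, since neither of these settings changes a ganglion array. In ganglion minus amacrine, Barhl2 was at 0.042 with floor 50, 0.20 weighted, 0.83 without E14.5 and E15.5 and 0.16 without E14.5, Meis2 at -0.21 with floor 50, -0.057 with the mean over probe sets, -1.13 weighted and -0.088 without the adult rod and B1, and Isl1 at 0.75 with medians and 1.20 weighted. For the photoreceptor contrast, Gnb1 was at -0.50 after quantile normalization, -0.70 weighted and -3.33 without the adult rod and B1, where Nsf was at -1.59, Rplp2 at 0.25 and Rps20 at -0.40. Adult minus P0, Crx was at -0.39, Neurod1 at -1.29 and Tulp1 at -1.17 after quantile normalization, and Crx at -1.34 with the mean over probe sets, which put Gnb1, P0 ganglion minus amacrine, at -0.50. Without single cells, Barhl2 ran from -1.21 to 1.12, Meis2 from -1.10 to 0.86, Isl1 from -1.15 to 1.37, Gnb1 from -3.36 to 2.58, Nsf from -1.75 to 3.62, Rplp2 from -3.53 to 0.22 and Rps20 from -0.33 to 2.89, the 4 last turning sign without the adult rod, and Gnb1 (-0.66) also without photoreceptor H1.

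Of the named genes of the fit, 4005 values kept direction and side of the threshold, 203 no longer passed and 46 newly passed.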

Other observations

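The tests of the globin and ribosomal patterns below were chosen after the results were seen.

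Some further genes varied between ganglion cells. In cells D8 and E1 of E14.5, which also held 7 of 9 lens genes, Cdk1, the mitotic kinase (10.8 and 12.9), and the progenitor factor Sox2 (13.2 and 13.7) were detected, as in no other ganglion cell. Ccna2, a cyclin of S phase (12.6 and 11.6), Mcm2, a replication helicase subunit (11.6 and 12.7), and Rrm2, which makes deoxynucleotides (12.2 and 12.7), were detected there too. They were not confined to these cells: Ccna2 was at 11.51 in F6 of E12.5 and 11.21 in A3 of E13.5, Mcm2 at 13.53 and 15.32 in B5 and C7 of E15.5, and Rrm2 at 12.18 in C6 of P0. Pcna was below the detection level in D8 (9.04). Ccnd1, a G1 cyclin, averaged 14.07 at E14.5 and 13.61 at E15.5, against 10.94 at E12.5 and 9.02 at P0. Sst, the peptide somatostatin, was at 14.40 and 12.59 in D8 and E1 and averaged 7.88 to 8.82 at the other ganglion stages. Isl1 averaged 13.01 at E12.5, 12.31 at E14.5, 15.08 at E15.5 and 11.12 at P0 and was at the floor in the cell of E13.5. These are values of 1 to 4 cells per stage, without a test.

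Transcripts of 2 embryonic globins were detected in the ganglion cells of E14.5 and E15.5. Hbb-y and Hba-x were detected in 5 of these 5 cells and in 0 of the 17 others, but the embryonic globin Hbb-bh1 in only 1 of the 5, and Alas2, an enzyme of haem synthesis in red cells, in 1 and 1. RNA from red blood cells may be the source, since Hbb-b2, an adult globin outside the list fixed in advance, was detected in 4 of the 5 cells and in 2 of the 17 others. Those 2 were amacrine cell J6 of E16.5 (14.16) and P0 photoreceptor E1 (13.31). J6 was also the outside cell with Alas2 (11.12), so blood transcripts were not confined to the ganglion cells. Transcription in the ganglion cells themselves stays open: 0 cells of other types held Hbb-y, but none of these was taken at E14.5 or E15.5. Stage and handling cannot be told apart here either.

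Ribosomal protein transcripts were lower in P0 than in E12.5 ganglion cells, at a median of -1.52. Array scaling is argued against by a median of -1.61 after quantile normalization. A lower cDNA yield of the P0 cells stays open, because scaling every array to the same trimmed mean also brings housekeeping genes (0.26) near 0. A stage effect may remain, as P0 amacrine cells differed from the amacrine cell of E16.5 by -1.35. It cannot be told apart from shared handling of the P0 cells, and the cell of E16.5 (13.96) lay near the highest P0 amacrine cell (13.86).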
